A study of Mus musculus with 6 samples.

How the data were processed

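The 6 mRNA sequencing libraries of mouse medullary thymic epithelial cells came from 2 groups, 3 from mice without Cre and an intact Trp53 gene (WT) and 3 from mice with a conditional deletion of Trp53 (cKO), the gene that encodes the transcription factor p53. Per the labels' protocols, thymi of mice aged 4 to 5 weeks were digested, cells carrying the epithelial surface protein EpCAM were enriched on magnetic beads, 75000 medullary cells per sample were sorted by flow cytometry straight into lysis buffer, and poly(A) RNA was made into strand-specific libraries that were read from both ends. The labels call the sorted population mTEChi, the mature medullary cells with high surface levels of class II MHC and co-stimulatory proteins. The labels do not name the Cre driver, and they do not say whether each library came from a separate animal, so the p-values measure the spread between these samples, which may be technical in part.

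The deposited count files hold whole-number counts of reads per gene with no normalization. Per the submitters' processing notes, reads were aligned with TopHat2 2.1.1 to the mouse genome build mm10 and handled with SAMtools 1.9, and Subread 2.0.1 is listed as the counting package. Per the file headers, the counts came from featureCounts 2.0.0 on the Ensembl release 99 annotation of GRCm38, summed over exons by gene, without regard to strand, and with a read that overlaps several genes counted for each of them. Per the file headers, the command had neither the option that counts read pairs nor the option that counts reads with several alignments. Each mate of a pair was therefore counted as a read, and reads that align equally well in several places were left out. Because strand was ignored, reads from overlapping and antisense genes cannot be told apart. The files give 1 count per gene and no count per exon, so reads from any Trp53 exons outside the deleted part are included in its count. All mitochondrial genes were listed at 0 in every library, so the mitochondrial share could not be used as a sign of RNA quality.

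A deposited table of the whole series holds the same counts for 51810 of the 55385 genes, equal in all 6 columns, and TPM values that the authors made from them. The deposited TPM matched counts per kilobase rescaled to a fixed sum, to within 0.000834% for values over 1. The 3575 genes found in the count files alone took 2.03% to 2.49% of the counts, and 1705 of them were pseudogenes by symbol or annotated type. The count files were used for every test, and the TPM values for that check only. Gene symbols came from the series table for 51810 genes and from a reference table of gene names for the other 3575. Coordinates are those of the count files, in mm10.

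Total counts were 45457892, 47469184 and 48564222 in WT libraries 1 to 3 and 47732508, 46500807 and 50128045 in cKO libraries 1 to 3. A floor of 3 counts corresponds to 0.0598 to 0.0660 CPM (counts scaled to the library total) in these libraries. Floors cover counting error only. No 2 libraries agreed within sampling noise: the chi-square per gene between libraries lay between 14.6 and 30.8, so all 6 were kept as separate samples.

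Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr, the robust quasi-likelihood fit and its F test. P-values were adjusted by the Benjamini-Hochberg method over the 28543 genes that passed the filter, with a threshold of 0.05 and no minimum fold change. Log2 fold changes are cKO over WT, standard errors (SE) are the log2 fold change divided by the square root of F, and CPM values are TMM scaled, given as mean ± SD of 3 libraries. Gene lists were fixed before the data were examined: p53 targets, S phase and mitosis, BCL2 family and caspases, mature and immature medullary cells, cortical epithelium, 8 lists of mimetic cells (tuft, microfold, keratinocyte, enterocyte and hepatocyte, neuroendocrine, ciliated, muscle, secretory and ionocyte), tissue antigens, 5 lists of other cell types (thymocyte, B cell, myeloid, fibroblast and endothelial, erythroid), stress, interferon, chromatin and p53 regulators, neighbours of Trp53, and sex-linked genes, which served only as a check. Mimetic cells are medullary epithelial cells that take on the expression programme of another tissue. Lists were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The fry test asked, by list, whether the members moved on balance in 1 direction and whether they moved in either. The number of genes detected at 1 CPM was counted after thinning every library to 45457892 counts, and the share of counts in the 23193 genes below the median of mean CPM was computed per library. Both were compared with a 2-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

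The genes named in the text followed a rule written before the data were examined. Trp53, Cdkn1a, Mdm2, Aire and Fezf2 were always named. To these came the up to 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 2 CPM, no overlap between groups and a regular symbol. Each list added up to 3 members past the threshold with the smallest p, or the member with the smallest p where none passed. This gave 39 genes. Any gene outside the rule was chosen after its values were seen, which includes Trp53-ps, Gm42047 and D630023F18Rik.

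The replicate numbers 1 to 3 occur in both groups. Deviations from the group means, over 22024 genes, correlated between same-numbered libraries with r = 0.234, 0.125 and 0.176, and every library correlated best with the library of its own number in the other group (the highest value between different numbers was 0.0862). The numbered pairing was therefore the closest in these data. With 3 libraries per group few pairings are possible, so chance alone could make it the closest. The labels do not say what a number stands for. The fit without the block had been chosen before the data were examined, and the fit with the replicate number as a block is given beside a result where it changes the call or moves a count by more than 1.5 times.

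On counts simulated from these libraries over 28543 genes, the edgeR test recovered 35.8% of 67 genes changed 1.5-fold, 70.1% of 67 changed 2-fold and 93.9% of 66 changed 4-fold, with 16 false calls among 149. DESeq2 recovered 47.8%, 76.1% and 95.5% of the same genes, with 39 false calls among 185. The changed genes were drawn only from those with a minimum count in every library. Camera at the preset correlation called 2% of 100 random lists of 36 unchanged genes at an unadjusted p under 0.05. With an estimated correlation it called 0% of them. Recovery of a changed list was not measured with an estimated correlation, so a lost call there does not show that a list was unchanged. The simulated genes varied independently of each other, so these rates do not cover lists whose members vary together.

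The alternatives tried were other scalings (relative log expression, upper quartile and library totals), DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, the fit without robust estimation, the replicate block, each library left out in turn, an adjusted p under 0.10, and the data without sex-linked, mitochondrial and haemoglobin genes. Lists were also tested with the estimated correlation and with fry. Detection was also counted at 0.5 and 5 CPM and without thinning, and the share of counts in low-expressed genes at other quartiles. Overlaps of exons were computed from the exon coordinates of the count files, which follow Ensembl release 99. Transcript GC content, lengths and sequences came from the GENCODE mouse annotation of the same build (release number 21). These steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.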

Results

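The data were read counts of 55385 mouse genes in 6 libraries of sorted mature medullary thymic epithelial cells (mTEChi), 3 from WT mice without Cre and 3 from mice with a conditional deletion of Trp53 (cKO). These cells transcribe genes of many other tissues and display their products to developing T cells, which removes or diverts self-reactive cells. The library totals lay between 45457892 and 50128045 counts, so depth differed little between groups. The title of the series ties repression of p53 in thymic epithelium to noise in chromatin accessibility, and the comparison of cKO with WT asks what loss of p53 does to the transcriptome of these cells.

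The deleted gene was the most changed by p-value. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873 in mm10) had 5351, 4837 and 5314 counts in the WT libraries and 386, 361 and 369 in the cKO libraries, so every library matched its label. Its level was 109 ± 6.83 CPM in WT and 7.80 ± 0.395 CPM in cKO (SD, n = 3 each), 14.0-fold lower (log2 fold change −3.81, SE 0.0999, edgeR adjusted p = 5.76e-10). The count covers all exons of the gene, and the files do not show which exons the remaining reads came from. Its processed pseudogene on chromosome 17, Trp53-ps, fell by 4.97 on the log2 scale (SE 0.257, adjusted p = 1.74e-06). That value is uncertain, because 41.0% of the 25-base words of Trp53-ps also occur in Trp53 transcripts. Reads that align equally well to both were left out, so this share does not measure reads counted for the wrong gene.

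Among canonical p53 target genes, 3 were lower in cKO past the threshold. Cdkn1a, which encodes the cell cycle inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), went from 233 ± 11.04 to 125 ± 6.22 CPM (1.86-fold lower, log2 fold change −0.90, SE 0.0782, adjusted p = 4.45e-04). Ccng1, the cyclin G1 gene (ENSMUSG00000020326, chromosome 11, 40748552 to 40755311), went from 212 ± 12.3 to 122 ± 4.93 CPM (log2 fold change −0.80, SE 0.0786, adjusted p = 0.00130). Psrc1, which encodes a protein of the mitotic spindle (chromosome 3, 108383839 to 108388231), went from 11.1 ± 1.61 to 4.07 ± 1.28 CPM (log2 fold change −1.45, SE 0.217, adjusted p = 0.0424). Of the 36 targets measured, these 3 fell, 0 rose and 33 did not pass over all genes tested, while 15 fell and 0 rose adjusted over the list alone. The median log2 fold change was −0.24, with 28 members below 0. Camera called the list lower at the preset correlation (adjusted p = 2.31e-12). With an estimated correlation its camera p was 0.0122, which did not pass after adjustment (adjusted p = 0.152). Fry gave adjusted p = 0.04997, or 0.157 with the replicate block. With the replicate number as a block, 8 targets fell and 1, Btg2, rose. The members that joined included Phlda3, an inhibitor of AKT signalling (log2 fold change −0.82, SE 0.0916, adjusted p = 1.43e-04 with the block and 0.0560 without it), and Gtse1 (−0.72, SE 0.132, adjusted p = 0.0152 with the block). Btg2, Phlda3 and Gtse1 were chosen after their values were seen. Mdm2, which encodes the ubiquitin ligase that degrades p53 and is itself a p53 target, had 149 ± 3.76 CPM in WT and 138 ± 4.29 in cKO (log2 fold change −0.12, SE 0.0738, adjusted p = 0.714) and did not pass.

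Over all 28543 genes tested, 17 passed the threshold, 7 higher and 10 lower in cKO, and in all 17 the 3 libraries of each group did not overlap. Among all tested genes 14.4% did not overlap, where chance gives 10%. At an unadjusted p under 0.05 there were 1222 higher and 1207 lower genes. With the replicate number as a block, 203 genes passed, 138 higher and 65 lower, the 17 included. Leaving out WT library 1, WT library 3 or cKO library 2 left 7, 6 and 7 calls.

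Outside the target list, further named genes past the threshold fell. These were Inka2, which encodes an inhibitor of the kinase PAK4 (ENSMUSG00000048458, chromosome 3, 105704599 to 105720842), from 8.18 ± 1.96 to 3.11 ± 0.492 CPM (log2 fold change −1.40, SE 0.213, adjusted p = 0.0424), Psors1c2 on chromosome 17, from 136 ± 7.49 to 88.2 ± 7.15 CPM (−0.62, SE 0.0863, adjusted p = 0.0297), and Banf1 on chromosome 19, which encodes a DNA-binding protein of the nuclear envelope, from 143 ± 14.1 to 95.4 ± 5.62 CPM (−0.59, SE 0.0906, adjusted p = 0.0436). The Banf1 value is uncertain, because 28.6% of its exon bases overlap exons of Eif1ad and strand was ignored in counting. The remaining falls were in genes of unknown function, the noncoding Gm42047 (−1.45, adjusted p = 0.00165) and D630023F18Rik (−1.54, adjusted p = 0.0218), which shares 14.4% of its exon bases with Gm28845. Gm28845 had a mean of 31.8 counts, against 237 to 320 for D630023F18Rik in WT and 85 to 117 in cKO.

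The 7 genes that rose did so by at most 2.19-fold. Malrd1, which encodes an enterocyte protein involved in bile acid regulation (chromosome 2, 15526479 to 16255555), went from 9.17 ± 1.82 to 20.1 ± 3.48 CPM (log2 fold change 1.13, SE 0.171, adjusted p = 0.0424). Serpinb1c, a serine protease inhibitor gene with close paralogs (chromosome 13, 32881434 to 32898211), went from 29.6 ± 3.52 to 58.0 ± 10.5 CPM (0.97, SE 0.136, adjusted p = 0.0324), and reads shared with its paralogs were not counted. C3, the central complement component (chromosome 17, 57203970 to 57228136), went from 520 ± 59.7 to 864 ± 129 CPM (0.73, SE 0.113, adjusted p = 0.0489). Rises were also measured for Hpse2, related to heparanase (0.71, SE 0.109), the carbonic anhydrase gene Car12 (0.61, SE 0.0909) and Fndc7 (0.57, SE 0.0794), with adjusted p between 0.0297 and 0.0436. None of the 7 rises was called with limma-voom or without robust estimation, whereas Trp53, Trp53-ps, Cdkn1a, Ccng1 and Gm42047 were called in all 16 other fits and the other 12 genes in 7 to 12 of them.

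**Figure D1:**
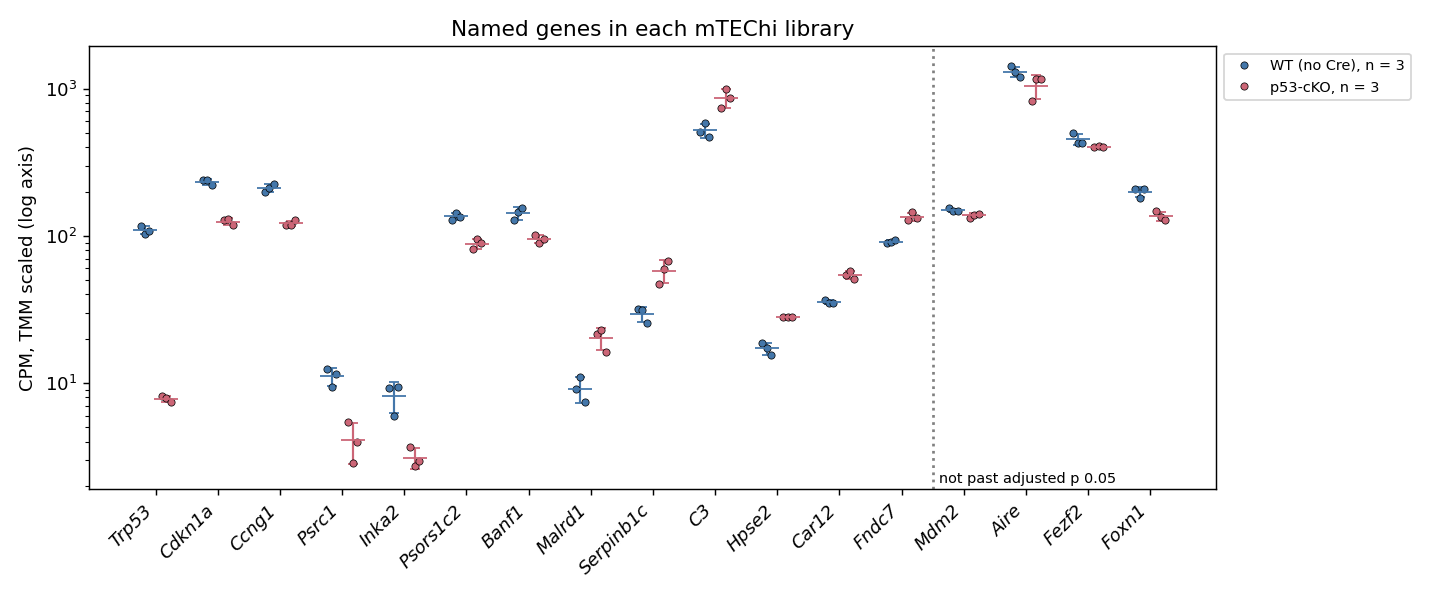
Expression of 17 genes in each of the 6 libraries, as TMM-scaled CPM on a log axis. Points are libraries, horizontal bars the means and whiskers the SD of 3 libraries per group (blue, WT; red, cKO). Trp53 lay between 7.38 and 8.16 CPM in cKO against 102 to 116 CPM in WT, and the 4 genes right of the dotted line did not pass the adjusted p threshold.

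No gene that defines mature medullary cells passed the threshold. Aire, the transcription factor that drives expression of tissue antigens in these cells (chromosome 10, 78030022 to 78043610), had 1307 ± 108 CPM in WT and 1047 ± 195 CPM in cKO (log2 fold change −0.32, SE 0.123, adjusted p = 0.516). cKO library 1 was the lowest at 822 CPM, against 1160 and 1159 in the other cKO libraries, and without it the log2 fold change was −0.17. Fezf2, another regulator of tissue antigens, had 453 ± 40.8 and 405 ± 3.07 CPM (−0.16, SE 0.0799, adjusted p = 0.612). None of the 24 measured members of the mature list passed over all genes; adjusted over the list alone 1 rose, the tight junction gene Cldn3 (log2 fold change 0.36, SE 0.0878, adjusted p = 0.246 over all genes). The camera adjusted p of this list was 0.131, but 0.00458 without WT library 2 and 0.0112 without cKO library 1. Of 16 genes of immature or junctional cells none passed (camera adjusted p = 0.799, and 0.0451 without cKO library 2), and Itga6 had the smallest p (0.15, SE 0.0837, adjusted p = 0.678).

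Foxn1, the transcription factor required for thymic epithelial development (ENSMUSG00000002057, chromosome 11, 78357577 to 78386558), had 199 ± 15.8 CPM in WT and 137 ± 9.64 CPM in cKO, lower in all 3 cKO libraries (log2 fold change −0.54, SE 0.0869). Its adjusted p was 0.0506 without and 0.00242 with the replicate block. DESeq2, upper-quartile scaling, scaling by library totals, no filter and the filter of 1 CPM in 3 libraries also called it, so it lay at the edge of the threshold. Of the 16 cortical epithelial genes none passed over all genes, and Foxn1 alone fell adjusted over the list alone, and the list as a whole was not called (median −0.05, camera adjusted p = 0.471). Among 14 genes next to Trp53 on chromosome 11, none passed without the block. Atp1b2 (chromosome 11, 69599736 to 69605942) had 16.8 ± 1.17 and 10.2 ± 1.24 CPM (−0.72, SE 0.134, adjusted p = 0.120 without and 0.00713 with the block). The neighbour list had a camera adjusted p of 0.357.

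The neuroendocrine, enterocyte and microfold lists of mimetic cells had positive medians in cKO. The neuroendocrine list had a median log2 fold change of 0.27, with 15 of 17 members above 0. None passed over all genes and 6 rose adjusted over the list alone, and with the replicate block 5 rose. Resp18, a gene of endocrine secretory cells, had 51.7 ± 11.3 CPM in WT and 93.1 ± 12.1 in cKO (log2 fold change 0.85, SE 0.157, adjusted p = 0.147 without and 6.62e-05 with the block). The enterocyte and hepatocyte list had a median of 0.20, with 21 of 22 members above 0. None passed over all genes, 3 rose adjusted over the list alone and 3 with the block. Muc13, a mucin gene of the intestinal surface, had 108 ± 7.17 and 145 ± 6.55 CPM (0.42, SE 0.0815, adjusted p = 0.142 without and 0.0139 with the block). The microfold list, named for the antigen-sampling cells of the gut, had a median of 0.26, with 10 of 11 members above 0. None passed over all genes, 2 rose adjusted over the list alone and 3 with the block, all of them chemokine genes. Ccl6 had 43.6 ± 8.29 and 69.1 ± 13.51 CPM (0.66, SE 0.162, adjusted p = 0.291 without and 8.51e-04 with the block).

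Camera called these lists higher at the preset correlation, with adjusted p = 1.05e-07 for neuroendocrine, 9.98e-07 for enterocyte and hepatocyte, and 3.10e-06 for microfold genes. With an estimated correlation the adjusted p were 0.113, 0.2498 and 0.2498 (camera p before adjustment 0.00453, 0.0445 and 0.04995). The preset correlation also called up to 13 of the 24 lists in splits of the 6 libraries that mixed the genotypes, against 6 in the real split. Mixed splits that parted the 2 libraries of every replicate number gave at most 7. The summed level of red cell markers was 87.5 CPM in WT and 68.6 CPM in the same cKO libraries. Ribosomal protein genes took 0.861% to 0.932% of the counts in WT and 0.740% to 0.819% in cKO, and pseudogenes 8.57% to 9.08% and 7.75% to 8.33%, with no overlap between the groups in either share.

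**Figure D2:**
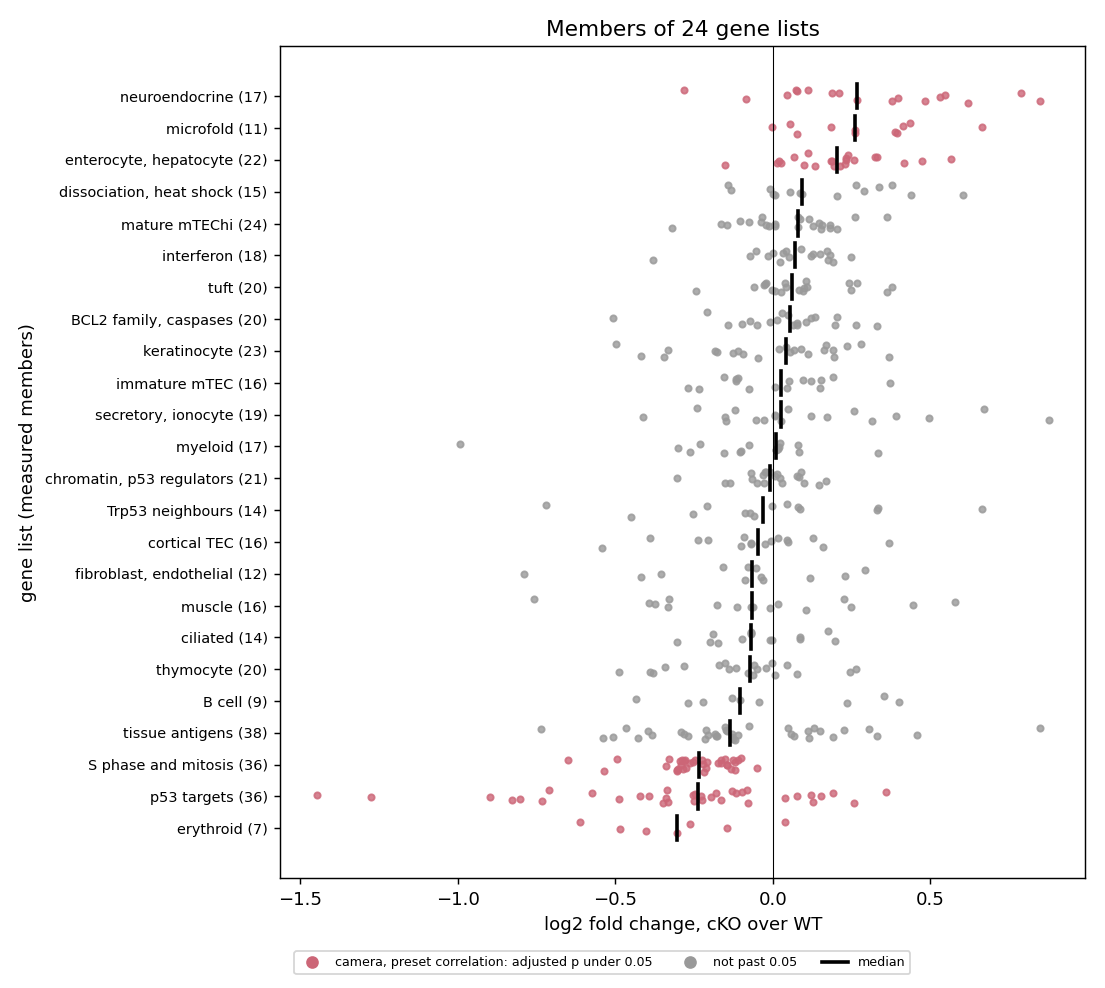
Log2 fold changes of cKO over WT for the measured members of 24 gene lists, 1 point per gene, with the number of members in parentheses. Vertical bars are medians, and red points belong to the 6 lists that camera called at the preset correlation. The medians ran from −0.30 for the erythroid list to 0.27 for the neuroendocrine list.

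The other mimetic lists were not called by camera, and none of their members passed over all genes. The tuft list had a median of 0.06 over 20 members (camera adjusted p = 0.471, and 1.71e-05, higher, without cKO library 3), and Dclk1 had the smallest p (0.27, SE 0.149, adjusted p = 0.680). The keratinocyte list had a median of 0.04, a mean of −0.01 and a camera adjusted p of 0.995 over 23 members, with Lor, a protein of the cornified envelope, at −0.50 (SE 0.145, adjusted p = 0.353). The ciliated list had a median of −0.07 over 14 members (camera adjusted p = 0.556), with Dnah5 at −0.30 (SE 0.109, adjusted p = 0.466). The muscle list had a median of −0.07 over 16 members (camera adjusted p = 0.654). Des, the desmin gene, had a log2 fold change of 0.44 (SE 0.120, adjusted p = 0.307 without and 0.0357 with the block), and 2 muscle genes rose with the block. The secretory and ionocyte list had a median of 0.02 over 19 members (camera adjusted p = 0.114, and 0.0119 without WT library 2 or 0.0316 without WT library 3), with 3 members higher adjusted over the list alone and 3 with the block. Cftr, the chloride channel gene, had 26.9 ± 2.40 and 42.8 ± 4.66 CPM (0.67, SE 0.111, adjusted p = 0.0605 without and 0.00482 with the block).

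Tissue antigens, the genes of other organs that these cells transcribe, were not called as a group. Of the 38 measured antigens none passed over all genes and 1, Resp18, rose adjusted over the list alone. The median log2 fold change was −0.14, with 25 members below 0, and the camera adjusted p was 0.455. The call changed with the libraries kept, with adjusted p = 0.0106 without WT library 1 and 0.00274 without cKO library 3, lower in cKO in both.

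All 36 genes of S phase and mitosis had negative log2 fold changes in cKO, with a median of −0.24. None passed over all genes by edgeR and 4 fell adjusted over the list alone. With the block 2 fell. Ube2c, which encodes a ubiquitin-conjugating enzyme of the anaphase-promoting complex, had 28.8 ± 5.75 CPM in WT and 18.4 ± 0.737 in cKO (−0.65, SE 0.141, adjusted p = 0.184 without and 0.0173 with the block). Of its exon bases 22.8% overlap exons of Tnnc2, but few of its reads can be shared. Shared reads were counted for both genes, and Tnnc2 had a mean of 24.3 counts against 870 to 1578 for Ube2c. Camera called the list lower at the preset correlation (adjusted p = 2.94e-13), with adjusted p = 0.316 with an estimated correlation, which was 0.377 for these genes. Of 20 BCL2 family and caspase genes none passed over all genes, and 1 rose and 1 fell adjusted over the list alone (median 0.06, camera adjusted p = 0.288). Hrk, a pro-apoptotic member, had 20.3 ± 1.74 and 14.3 ± 2.45 CPM (−0.51, SE 0.139, adjusted p = 0.310 without and 0.0460 with the block).

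No list of markers of other cell types was called higher in cKO. The camera adjusted p were 0.471 for 20 thymocyte genes (median −0.07), 0.894 for 9 B cell genes (−0.11), 0.628 for 17 myeloid genes (0.01) and 0.473 for 12 fibroblast and endothelial genes (−0.07), with no member past the threshold. Thymocyte genes were called lower without WT library 3 (5.36e-05) or cKO library 2 (0.00237), and myeloid genes without WT library 1 (0.0276). The members with the smallest p were Cd3e (−0.49, SE 0.347, adjusted p = 0.755), Ebf1 (0.35, SE 0.145, adjusted p = 0.537), Siglech (−0.99, SE 0.404, adjusted p = 0.536) and Col1a1 (−0.35, SE 0.123, adjusted p = 0.454). The B cell list had a negative median and mean while camera gave its direction as up. The 7 red cell genes had a median of −0.30 and were called lower (camera adjusted p = 0.00174, and adjusted p = 0.397 with an estimated correlation). Over all genes none of the 7 passed. Hba-a2, an alpha globin gene with a near-identical copy, had 22.8 ± 2.49 and 14.9 ± 3.90 CPM (−0.61, SE 0.175, adjusted p = 0.341 without and 0.0221 with the block).

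Genes of dissociation and heat shock had a median of 0.09 (15 members, camera adjusted p = 0.132), 2.59e-04 with the block, 6.55e-04 without WT library 1 and 5.35e-04 without cKO library 3. Hspa1b, which has a close paralog, had −0.13 (SE 0.117, adjusted p = 0.814). Interferon-stimulated genes had a median of 0.07 (18 members, camera adjusted p = 0.0773), 0.0365 with the block, 3.43e-04 without WT library 3 and 1.16e-04 without cKO library 2. Gbp2 had 0.25 (SE 0.0891, adjusted p = 0.470). With the block and an estimated correlation both lists had an adjusted p of 0.548. The 21 chromatin and p53 regulators had a median of −0.01 (camera adjusted p = 0.921), and Mdm4, which encodes an inhibitor of p53, had 235 ± 31.7 and 191 ± 6.14 CPM (−0.30, SE 0.0946, adjusted p = 0.396). Sex-linked genes were used only as a check. All 5 had positive log2 fold changes in cKO, with a median of 0.18, and none passed over all genes. Camera called them higher at the preset correlation (adjusted p = 0.00478), with adjusted p = 0.2498 with an estimated correlation. Xist and the Y-linked genes moved in the same direction, and what this says about the sex of the animals was not tested.

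The number of detected genes was on average lower in cKO, in an exact test that cannot go below p = 0.1 with these groups. At equal depth 22113 ± 11.6 genes reached 1 CPM in WT and 21879 ± 275 in cKO (SD, n = 3 each), a difference of −234 genes with an exact permutation p of 0.4. The cKO libraries had 21602, 21882 and 22152 genes, a wider spread than the WT libraries, which had 22102, 22125 and 22111. The genes below the median expression level took 0.324% ± 0.00517 of the counts in WT and 0.303% ± 0.0307 in cKO, a difference of −0.0214 percentage points with an exact permutation p of 0.4. At 5 CPM there were 15847 genes in WT and 15677 in cKO, with every cKO library below every WT library (difference −170, exact permutation p = 0.1). The share of counts in genes below the third quartile also lay lower in every cKO library (5.66% and 5.45%, exact permutation p = 0.1). Without cKO library 1 the differences at 1 CPM and below the median were −95.7 genes and −0.00772 percentage points. The median log2 fold change ran from −0.08 in the lowest decile of mean expression to 0.04 in the highest.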

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

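Removal of GC and length trends, the data without pseudogenes, and the replicate block combined with the estimated correlation, with fry or with trend removal were chosen after the data were seen. The replicate block for the share of counts was also chosen then. The other alternatives were set beforehand.

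The 39 named genes kept their direction in all 621 refits, with 0 sign changes, and 513 stayed on the same side of the threshold, while 79 lost and 29 gained a call. The 17 genes were called in varying number. DESeq2 called 180 genes (131 higher, 49 lower), limma-voom 5 (0 and 5), no filter on low counts 160 (108 and 52), the fit without robust estimation 6 (0 and 6), and the replicate block 203 (138 and 65). An adjusted p under 0.10 gave 31 (16 higher), by its looser threshold, and 11 genes were higher without pseudogenes. For the tools, the filter and the block the cause was not tested. With fewer samples, leaving out each library gave 6 to 16 genes, 0 to 7 higher and 5 to 9 lower. The p53 targets that fell numbered 9 with DESeq2, 8 without a filter and 8 with the block, against 3. The other scalings gave 18 or 19 genes. Counts of list members moved by more than 1.5 times in 36 of 768 refits.

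The lists for p53 targets, cell cycle, microfold, enterocyte and hepatocyte, neuroendocrine and erythroid genes kept their direction in every refit and were called in each with a left-out library, another scaling, another filter, the block or trend removal at the preset correlation. In that order, their adjusted p with an estimated correlation were 0.152, 0.316, 0.2498, 0.2498, 0.113 and 0.397, and 0.459, 0.490, 0.295, 0.459, 0.295 and 0.490 with the replicate block. Those of fry with the replicate block were 0.157, 0.368, 0.154, 0.368, 0.154 and 0.368. Fry without the block gave 0.247 for cell cycle, 0.272 for microfold, 0.361 for enterocyte and 0.361 for erythroid genes, and its mixed test 0.0835, 0.182, 0.291 and 0.217. With the replicate block the mixed test gave 0.146, 0.0332, 0.0332 and 0.108, so microfold and enterocyte genes passed it only with the block. A higher correlation assumed between members lowers the evidence in camera by construction, as for cell cycle genes, with an estimate of 0.377 against the preset 0.01. That cannot account for neuroendocrine genes, whose estimate was 0.00856. Their camera p before adjustment went from 1.25e-08 at the preset correlation to 0.00453. Nor can a higher correlation account for microfold (−0.0592) and neuroendocrine (−0.0365) genes with the block. A call lost with the estimated correlation is therefore not by itself evidence that members vary together. For the neuroendocrine and microfold lists, and for fry, the cause was not tested.

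Other lists gained a call in places, and the cause was not tested. The mixed fry test gave 0.0322 for BCL2 family, 0.0275 for secretory and 0.0322 for neighbour genes. With the replicate block it gave 0.0332 for cortical, 0.0140 for muscle, 0.0332 for secretory, 0.0332 for tissue antigen, 0.0140 for fibroblast and endothelial, 0.0140 for interferon and 0.0332 for neighbour genes, and BCL2 family genes did not pass (0.0549). No filter gave 0.0376 for interferon genes. The replicate block gave 2.59e-04 for stress and 0.0365 for interferon genes. Trend removal gave 0.0173 for mature medullary, 0.0308 for secretory and 0.0173 for stress genes. Trend removal with the replicate block gave 0.0125 for mature medullary, 0.0373 for tuft, 0.0232 for secretory, 2.12e-06 for stress and 0.0373 for interferon genes. Directions of 11 of the 24 lists switched in some refit, never past the threshold. Keratinocyte genes switched with fry (0.945), the 1 CPM filter (0.923), the block (0.909), and the block with an estimated correlation (0.962) or fry (0.948). Over the left-out libraries the adjusted p ranged from 0.338 to 0.896 for keratinocyte, 0.00274 to 0.9996 for tissue antigen, 0.0276 to 0.973 for myeloid, 5.35e-04 to 0.973 for stress, 0.00458 to 0.667 for mature medullary, 0.0119 to 0.531 for secretory, 5.36e-05 to 0.578 for thymocyte, 1.16e-04 to 0.698 for interferon, 0.0451 to 0.837 for immature medullary, 1.71e-05 to 0.807 for tuft, 0.136 to 0.973 for B cell, 0.161 to 0.973 for chromatin, 0.119 to 0.973 for ciliated and 0.328 to 0.973 for muscle genes.

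Detection and the share of counts in low-expressed genes kept their direction, lower in cKO, under all their alternatives, from −370.7 genes without cKO library 3 to −95.7 without cKO library 1. At 5 CPM, and for genes below the third quartile, the exact permutation p was 0.1, the smallest possible. In counts simulated at this depth and sample size edgeR recovered 35.8% of genes changed 1.5-fold, and neither depth nor sample size was varied.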

Other observations

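The tests of the split count of 17 genes, of Trp53-ps, of a lower share of the main cell type, of admixed cells and of blocked calls on chromosome 11 were chosen after those results were seen. The genes named next were also chosen after their values were seen.

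Cdh17, an intestinal cadherin gene, had 132 ± 13.8 CPM in WT and 201 ± 18.1 CPM in cKO (0.60, SE 0.0960, adjusted p = 0.0505 without and 5.31e-04 with the block). Dapl1 varied widely within both groups, with 49.3 ± 18.7 and 25.9 ± 13.4 CPM and an adjusted p of 0.707, yet it was among the most significant genes with the block (−0.98, SE 0.1003, adjusted p = 6.62e-05).

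The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 17 genes and the highest other split also 17, so 2 splits gave as many. That other split set WT 1, WT 3 and cKO 1 against the rest and parted 1 numbered pair, whereas the real split parted 3. Among the 4 splits that part all 3 pairs, the highest other count was 1 without the block. With the block the real split gave 203 genes and the highest other 3, so 1 of these 4 splits reached the count, again too few splits for a share under 0.05. For the gene lists called by camera, the real split gave 6 and the highest other 13, and 8 of the 10 splits gave at least 6; among the 4 pair-parting splits the highest other was 7. The p53 target list had a camera adjusted p of 2.22e-12 in the real split and 4.47e-05 at the lowest in the others. It was under 0.05 in some of the others too. With the block the real split gave 8 lists and the highest other of its 4 splits also 8.

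Foxn1 and Slc6a4, the serotonin transporter gene, were both lower in cKO and both lie on chromosome 11 with Trp53. Slc6a4 (76998603 to 77032340) had 283 ± 7.82 and 209 ± 8.36 CPM (log2 fold change −0.44, SE 0.0731, adjusted p = 0.0627 without and 0.00813 with the block). Differences in DNA carried along with an allele would raise the share of differing genes nearby, but 7.54% of the 650 tested genes within 10 Mb of Foxn1 or Trp53 had an unadjusted p under 0.05, against 8.53% elsewhere (Fisher's exact p = 0.434), and 11.4% against 11.8% with the block (Fisher's exact p = 0.806), which argues against a broad block of linked differences. Leaving out Foxn1, Slc6a4 and Atp1b2, which prompted the question, 7 of 647 genes there passed with the block, 1.08% against 0.688% elsewhere (Fisher's exact p = 0.225), Ccl6 and Ccl9 of the microfold list among them. For Atp1b2, reads from annotated Trp53 exons counted for an overlapping neighbour are ruled out by 0 shared exon bases with Trp53. Reads from beyond the annotated end of Trp53 were not examined. A variant acting on single genes such as Foxn1 or Slc6a4, an effect of Cre or its insertion site, which no control carries, and an effect of p53 loss stay open.

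Camera called the neuroendocrine, enterocyte and microfold lists higher and the cell cycle list lower in cKO at the preset correlation, but their adjusted p were 0.113, 0.2498, 0.2498 and 0.316 with an estimated correlation. A GC or length trend is argued against, since each of these 4 lists kept at least 0.892 of its median log2 fold change after the trends were removed and all 4 stayed called at the preset correlation. A lower share of the main cell type would raise the markers of every other type alike. The 13 lists of mimetic and other cell types moved apart by more than their spread between numbered pairs (F = 5.37). The limit of F was 2.18, and the other splits that part all pairs gave at most 1.12. The 13 lists include the 3 whose rise prompted the question, so a high F was partly fixed beforehand. The test therefore cannot decide on this explanation. For thymocytes, B cells or red cells mixed into the cKO libraries, the highest median of the markers was −0.0717, in the thymocyte list (SD of members 0.199). All 3 medians lay below the 0.204 of the enterocyte list by more than the SD of the members. That SD is a spread between genes, not between libraries. Within the numbered pairs red cell markers were not higher in any (−0.454, −0.564 and −0.0018), which argues against added red cells. Thymocyte markers (−0.115, −0.197 and 0.0286) and B cell markers (0.126, −0.289 and 0.158) went both ways, so those cells are not excluded. Myeloid cells, fibroblasts or endothelial cells cannot be told apart from the change. Their highest median, 0.00985 in the myeloid list, came from members that went both ways (SD 0.276). Enrichment and sorting for medullary epithelial cells would deplete them. Such cells, thymocytes or B cells, a lower share of the main cell type, more of the 3 mimetic types and an unrecorded difference between mice stay open. So do the split counts above. A change in mimetic cells is therefore a hypothesis.

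If whole programmes had moved, genes outside the fixed lists would move too, which was tested on a second list for each. A second list of 36 cell cycle genes was lower (35 of 36 below 0, median −0.22, camera p = 3.55e-11 at the preset correlation, but p = 0.0892 with an estimated correlation). Such genes rise and fall together between libraries, so the second list is not independent of the first. A second list of 36 enterocyte genes had a camera p of 0.0346 at the preset correlation, or 0.0519 adjusted over the second lists, and p = 0.0760 with an estimated correlation (23 of 36 above 0, median 0.06), and p = 0.0633 at the preset correlation with the replicate block, which leaves open whether that programme moved. A second list of 33 neuroendocrine genes was not called by camera (p = 0.554 at the preset correlation, 17 of 33 above 0), which counts against a rise of that programme as a whole.

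Trp53-ps fell with Trp53. Reads shared with Trp53 are a candidate explanation, but 41.0% of the 25-base words of Trp53-ps occur in Trp53 transcripts, between the bounds set for and against it. That share does not measure reads counted for the wrong gene, since reads that align equally well to both were left out. Shared reads and a change of the pseudogene itself therefore cannot be told apart without the alignments.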
